A study of Homo sapiens with 12 samples.

How the data were processed

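RNA was measured in 12 libraries labelled as HS578T, an established triple-negative breast cancer cell line, 48 h after vehicle (DMSO) or doxorubicin, an anthracycline that poisons DNA topoisomerase. Per the labels, the cells had either an intact short arm of chromosome 17 (17p) or a heterozygous loss of it, with 3 libraries in each of the 4 groups. The sample titles name the intact libraries as Cas9 and the deleted ones as 17PKO. Per the labels, treated intact cells received 170 nM and treated deleted cells 1 µM, a ratio of 5.88. Genotype and dose therefore change together in every comparison of treated libraries between the genotypes and in the difference of the doxorubicin effects. Any other difference between the cell populations also goes with the genotype label in these comparisons and in DMSO.

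The deposited values are raw counts per gene, 1 column per library. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.7.9a and counted with featureCounts of Subread 2.0.1. The annotation release and the strand setting of the counting are not given in the sources used here. Genes with an overlapping or antisense partner, and genes that share reads with near-identical copies, such as ribosomal protein and histone genes, are uncertain for that reason. Of 60660 gene identifiers 58429 had a position in GENCODE 29, on hg38, and 60419 a symbol.

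Library totals ran from 66150539 to 99142099 counts. At this depth 3 counts, the floor for a gene at 0, stood for 0.0303 to 0.0454 CPM (counts per 1e6). Floors cover counting error only. The bootstrap interval of 17p covers the spread between genes, and standard errors and bounds of fold changes come from the fit and include the spread between libraries. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Within groups, pairs of libraries differed by more than sampling noise, with chi-square per degree of freedom from 8.42 to 204, and none was counted as a duplicate.

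Genes were filtered with filterByExpr, scaled by trimmed mean of M values and tested in 1 quasi-likelihood fit of the 4 groups in edgeR 4.0.16 (R 4.3.3), which tested 21803 genes. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05. The standard error (SE) of a log2 fold change is its size divided by the root of the F statistic. The comparisons were the genotype effect in DMSO, the doxorubicin effect in each genotype, the genotype effect in doxorubicin and the difference of the doxorubicin effects. 21 gene lists were tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. The dose of 17p was the median log2 fold change of genes that start before 23 Mb on chromosome 17 less that of all other genes, with a 95% bootstrap interval over genes from 2000 draws. The score of a library was the mean over these genes of log2(CPM + 1), less each gene's mean in the intact DMSO libraries. It was tested by an exact two-sided permutation of genotype within treatment over 400 arrangements, whose smallest possible p is 0.005.

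The groups, comparisons, tests, gene lists, first set of alternatives and rule for named genes were fixed before the data were examined. The rule named a fixed set in each comparison, of which POLR2A, CDKN1A, MDM2, TOP2A and ABCB1 are given; some genes that the rule takes are not reported here. It added the 5 largest and 5 smallest log2 fold changes among genes past the threshold with no overlap between libraries, at least 5 CPM in the higher group and no clone-based or LINC symbol; overlap was not asked of the difference of effects. From each list it added up to 2 members with the lowest p among those past the threshold and the most abundant member that did not pass. Not all of these are named, and genes near 0 counts in a group were mostly left out because their fold change depends on the prior count. ABCB1, which encodes a drug efflux pump, was not tested, with 24 counts over the 12 libraries and at most 6 in a library.

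The alternatives were RLE size factors and library totals as the scaling, no filter and a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, a 2-fold change as well, leaving out the 10 most abundant genes, other definitions of 17p, fry in place of camera, list members on 17p left out, and leaving out each library. Removing the trend of each library with transcript GC content by loess offsets (span 0.5), and leaving out together the 2 libraries with the highest mitochondrial share, were chosen after seeing the data. GC content was known for 98.0% of the genes tested.

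The fit was tested on simulated counts with 200 genes changed, drawn from the real means, dispersions and library sizes. The changed genes were taken only from those above a minimum mean count. Each gene was drawn independently, without the GC trends that genes of a library share. The shares below may therefore not hold for genes of low counts or for the real libraries. With 200 genes changed, the adjusted threshold also asks a lower unadjusted p than in real comparisons where many more genes passed. For the genotype effect in DMSO 86 of 100 genes changed 2-fold and 35 of 100 changed 1.5-fold were called over 21115 genes, and 13 of the 134 calls were unchanged genes (9.70%). For doxorubicin in 17p-intact cells 80 of 100 genes changed 2-fold and 29 of 100 changed 1.5-fold were called over 21136 genes, and 9 of the 118 calls were unchanged genes (7.63%). For doxorubicin in 17p-deleted cells 75 of 100 genes changed 2-fold and 32 of 100 changed 1.5-fold were called over 21138 genes, and 2 of the 109 calls were unchanged genes (1.83%). For the genotype effect in doxorubicin 81 of 100 genes changed 2-fold and 25 of 100 changed 1.5-fold were called over 21121 genes, and 5 of the 111 calls were unchanged genes (4.50%). For the difference of the doxorubicin effects 53 of 100 genes changed 2-fold and 2 of 100 changed 1.5-fold were called over 21105 genes, and 1 of the 56 calls were unchanged genes (1.79%).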

Results

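Gene-level RNA-seq counts were obtained from cells labelled as HS578T, a triple-negative breast cancer line, with and without a labelled heterozygous loss of 17p. The libraries formed 4 groups of 3. Total counts were 68064971 to 96798057 for cells labelled 17p-intact in DMSO and 66150539 to 78785434 for cells labelled 17p-deleted in DMSO. They were 81966803 to 99142099 for intact cells in 170 nM doxorubicin and 76508178 to 92932596 for deleted cells in 1 µM doxorubicin. In a check of chromosome-specific transcripts, 12 of 12 libraries did not match the karyotype recorded for that line, so the cells are named only as the labels name them and their identity was not settled here.

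Libraries of a group differed unevenly. Mitochondrial genes took 6.90% of the counts in replicate 2 of the deleted DMSO group and 5.54% in replicate 1 of the intact doxorubicin group. The deviations of genes from their group mean had a Spearman rho with transcript GC content of -0.746 and -0.686 in these libraries. It ran from -0.345 to 0.730 in the other libraries, and their mitochondrial share from 2.61% to 3.57%. Deviations are taken from the mean of a library's own group, so a strong trend in a single library gives the opposite sign in its partners. A large rho of opposite sign therefore need not be a trend of that library itself. This rho is across genes, which are not independent replicates. By the SD of the log2 deviations replicate 2 of the intact doxorubicin group, with a rho of 0.730, lay farther from its group, at 0.254, than replicates 1 and 3, at 0.205 and 0.134. Replicate 2 of the deleted DMSO group was at 0.308, against 0.158 and 0.179.

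**Figure D1:**
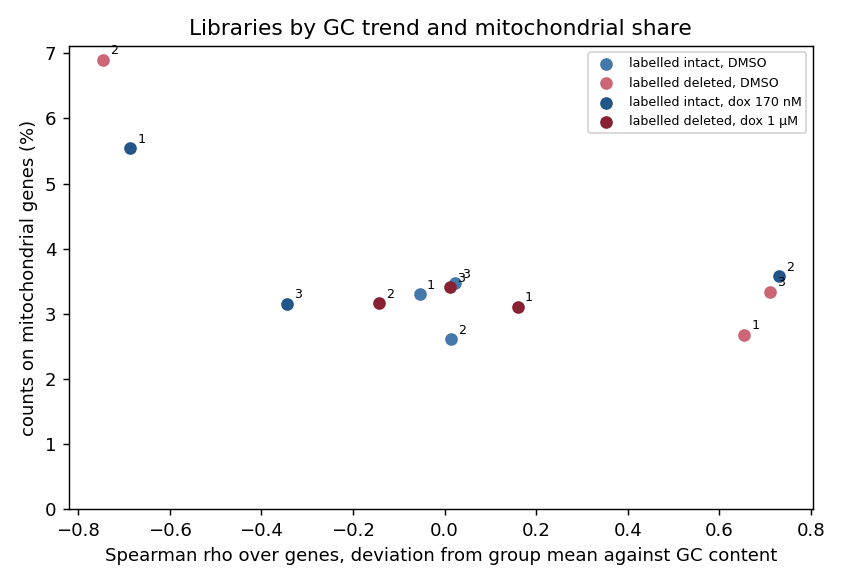
Each point is a library, numbered by replicate; the x axis is the Spearman rho over genes between deviation from the group mean and GC content, the y axis the percent of counts on mitochondrial genes. Replicate 2 of the deleted DMSO group, at 6.90%, and replicate 1 of the intact doxorubicin group, at 5.54%, lie highest.

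The first question was whether RNA from 17p was lower in the libraries labelled as lacking one copy. POLR2A, a 17p gene that encodes the largest subunit of RNA polymerase II (ENSG00000181222.19, chromosome 17, 7484366 to 7514616, hg38), was at 482 ± 47.1 CPM (SD, n = 3) in the intact and 602 ± 157 CPM in the deleted DMSO libraries. It did not pass, with an edgeR log2 fold change of 0.32, SE 0.16 (adjusted p = 0.150). Replicate 2 of the deleted group held 780 CPM against 543 and 483 in the others, and without it the change was 0.07 (adjusted p = 0.707 by edgeR). Without replicate 3 of that group it was 0.46 and just past the threshold by edgeR. Over 399 genes of 17p the median log2 fold change was -0.12 against 0.04 for all other genes, a difference of -0.17 (95% interval -0.23 to -0.10, over genes and not over libraries). Without replicate 2 of the deleted DMSO group the difference was -0.11. The 974 genes of 17q, which the labels do not name as lost, had a lower median of -0.24.

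The mean 17p score was -0.10 in the deleted and, by construction, 0.00 in the intact DMSO libraries, with each deleted library below each intact one. In doxorubicin it was 0.01 in the deleted and -0.01 in the intact libraries, the opposite order. There the libraries overlapped, with replicate 2 of the intact group, at 0.05, above each deleted one. The score less that of all other genes was -0.05 in the deleted and -0.01 in the intact doxorubicin libraries, the same order as in DMSO. These libraries overlapped as well, with replicate 1 of the intact group, at -0.050, below replicate 2 of the deleted group, at -0.043. The exact permutation test of the mean 17p score over both treatments gave two-sided p = 0.24, and p = 0.02 by the same exact test with the fixed lists or with genes of at least 5 CPM. With library totals as the scaling the exact p of that score was 0.705. Other scores were tested in the same way by exact permutation, with p = 0.01 for 17p less all other genes, which was negative, and p = 0.005, the smallest possible, for 17p less 17q, which was positive. By band, the fixed lists of 17p genes differed from other genes by 0.01 at 17p13.3, -0.14 at 17p13.2, -0.31 at 17p13.1, -0.37 at 17p12 and -0.17 at 17p11.2. In doxorubicin the difference over 17p was -0.06 (95% interval -0.12 to 0.03) with the annotated genes and -0.15 (-0.29 to -0.08) with the fixed lists. By band it was 0.10 (-0.12 to 0.46) at 17p13.3, -0.40 (-0.50 to -0.08) at 17p13.2, -0.42 (-0.55 to -0.28) at 17p13.1, -0.20 (-0.70 to -0.02) at 17p12 and -0.03 (-0.11 to 0.21) at 17p11.2. POLR2A and 17p as a whole did not follow the label as a loss of 1 of 2 copies would, and groups are named by their labels throughout.

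**Figure D2:**
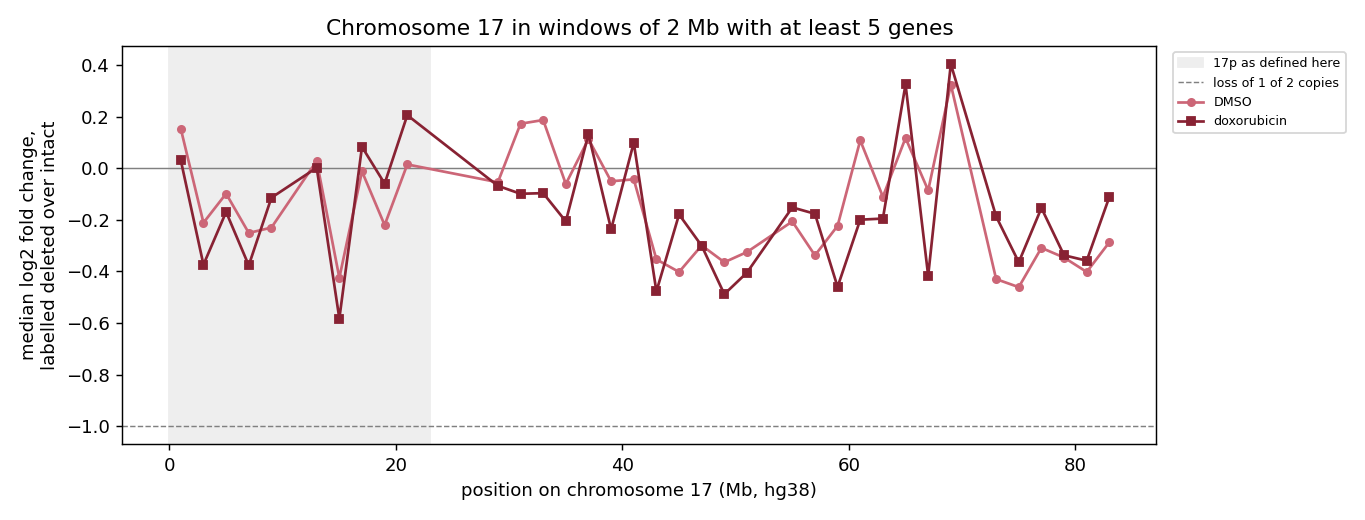
The y axis is the median log2 fold change of libraries labelled deleted over those labelled intact in windows of 2 Mb along chromosome 17 (x axis, Mb, hg38) with at least 5 genes, in DMSO and in doxorubicin; shading marks 17p and the dashed line the loss of 1 of 2 copies. In DMSO the windows on 17p lie between -0.42 and 0.15, and no window reaches the dashed line.

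In DMSO, interferon-stimulated and antigen presentation genes were lower in the libraries labelled 17p-deleted. Of 36 interferon-stimulated genes 29 fell, 1 rose and 6 did not pass, with 31 lower adjusted over the list alone and a median of -1.01. OAS2, an antiviral enzyme that senses double-stranded RNA, went from 20.1 to 3.20 CPM (-2.65, SE 0.11) and MX2, an antiviral GTPase, from 11.5 to 3.24 CPM (-1.82, SE 0.10). Of 18 antigen presentation genes 16 fell (17 lower and 1 higher adjusted over the list alone), with a median of -1.21. ERAP2, which trims peptides, was at -1.65, SE 0.11 and TAPBP, which helps load them on HLA class I, at -1.24, SE 0.08. Of 34 mesenchymal and matrix genes 16 fell and 6 rose, the same counts adjusted over the list alone, with MMP2, a matrix metalloproteinase, at -3.20, SE 0.14 and TNC, a matrix glycoprotein, at -1.84, SE 0.10.

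In all, 4092 genes were higher and 3526 lower by edgeR. RTN1 went from 2.71 to 48.4 CPM and GPNMB, a membrane glycoprotein, from 2.72 to 45.3 CPM. CAMK4, a calcium-dependent kinase, went from 27.4 to 0.609 CPM. MDM2, a ubiquitin ligase gene (ENSG00000135679.25, chromosome 12, 68808176 to 68850686), rose by 0.76 (SE 0.14), and CDKN1A, which encodes the cell cycle inhibitor p21 (ENSG00000124762.14, chromosome 6, 36676460 to 36687339), was at 0.13, SE 0.17 (adjusted p = 0.609). TOP2A, the topoisomerase that doxorubicin targets (ENSG00000131747.15, chromosome 17, 40388516 to 40417950), was at 0.26, SE 0.09 (adjusted p = 0.0445), a call that was lost under most of the alternatives.

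The 3 lists above passed camera at both correlations, with adjusted p = 9.63e-04, 9.63e-04 and 0.0294 with an estimated correlation. With the GC trend removed the mesenchymal list had adjusted p = 0.191 with an estimated correlation. Other lists passed at the preset correlation alone. G2/M genes had 19 of 35 higher and 3 lower (21 and 3 adjusted over the list alone; adjusted p = 0.314 with an estimated correlation), among them FOXM1 at 0.58. NF-kB and inflammatory genes had 10 of 26 lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 0.0920 with an estimated correlation), with the chemokine CXCL8 at -1.52, and the 1 member that rose was the adhesion gene ICAM1 at 1.39. NRF2 targets had 9 of 21 lower and 2 higher (9 and 3 adjusted over the list alone; adjusted p = 0.0911 with an estimated correlation), with NQO1, a quinone reductase, at -2.26. Ribosomal protein genes had 15 of 42 lower and 1 higher (16 and 1 adjusted over the list alone; adjusted p = 0.747 with an estimated correlation). Anthracycline transport and metabolism genes had 8 higher and 8 lower of 25 (9 and 8 adjusted over the list alone; adjusted p = 0.491 with an estimated correlation). The fixed 17p lists had 59 of 201 lower and 25 higher (59 and 26 adjusted over the list alone; adjusted p = 0.630 with an estimated correlation), with XAF1 at -3.88 and TRIM16 at -1.42. With the GC trend removed camera gave adjusted p = 0.107 for the 17p lists and 0.154 for the anthracycline genes at the preset correlation. G1/S genes, histones, apoptosis regulators and DNA sensing genes, which did not pass, differed in sign between median, mean and test. The p53 targets did not pass camera either (adjusted p = 0.476 at the preset correlation), while the fry test gave adjusted p = 0.0158. Of 32 p53 targets 6 were higher and 4 lower (6 and 3 adjusted over the list alone), with a median of 0.12. The deleted DMSO group holds the library with 6.90% mitochondrial counts.

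The next question was what 170 nM doxorubicin changed in cells labelled 17p-intact. Interferon-stimulated genes were among the few that rose, with MX2 at 0.80, SE 0.09 (adjusted p = 0.00965), MX1 at 0.71, SE 0.08, OAS2 at 0.71, SE 0.10 and IFIT1 at 0.59, SE 0.09. NTRK3, a neurotrophin receptor, fell from 6.15 to 2.84 CPM (-1.11, SE 0.17) and CXCL12, a chemokine, from 16.9 to 10.0 CPM (-0.75, SE 0.11). CDKN1A was at 66.6 CPM in DMSO and 77.2 CPM in doxorubicin (0.21, SE 0.17, adjusted p = 0.668), and MDM2 at 117 and 125 CPM (0.09, SE 0.14, adjusted p = 0.845). TOP2A was at 0.52, SE 0.09 (adjusted p = 0.0588). It passed with the GC trend removed, at 0.45, SE 0.06 (adjusted p = 0.00402). It also passed with DESeq2, limma-voom, library totals or no filter, without replicate 2 of the deleted DMSO or of the intact doxorubicin group, and without the 2 libraries of the highest mitochondrial share, and not under the other alternatives.

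By list, interferon-stimulated genes had 4 of 36 higher (21 adjusted over the list alone), with a median of 0.46. G2/M genes had 0 of 35 past the threshold by edgeR and 31 higher adjusted over the list alone, with a median of 0.40. Mesenchymal genes had 2 of 34 lower (14 adjusted over the list alone), among them the matrix glycoprotein gene THBS1 at -0.53, SE 0.08. These lists passed camera with adjusted p = 6.17e-04, 8.23e-04 and 5.71e-04 with an estimated correlation. Of 32 p53 targets 0 passed by edgeR and 3 were higher adjusted over the list alone, with a median of 0.07. With the GC trend removed 2 of the 32 were higher and 0 lower, with a median of 0.06. Camera then gave adjusted p = 0.122 for the p53 targets at the preset correlation. Mitochondrially encoded mRNAs had a median of 0.52 with 0 of 13 past the threshold (adjusted p = 0.719 with an estimated correlation), and replicate 1 of the treated group held 5.54% mitochondrial counts. Cytosolic DNA sensing genes had 0 of 9 past the threshold and 1 adjusted over the list alone (adjusted p = 0.0943 with an estimated correlation). Once the GC trend was removed, 15 of 36 interferon-stimulated and 18 of 35 G2/M genes were higher and 7 of 34 mesenchymal genes lower, and these lists passed with an estimated correlation (adjusted p = 7.97e-05, 3.37e-05 and 0.00170). G1/S genes and the 17p lists then also passed at the preset correlation (adjusted p = 0.0306 and 0.0236), with adjusted p = 0.385 and 0.243 with an estimated correlation. Cholesterol synthesis genes, which did not pass, had a positive median and a negative mean and test.

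In all, 6 genes rose and 7 fell by edgeR, and 2504 had an unadjusted p under 0.05. The count was 0 when only the groups compared were fitted and 467 with DESeq2, and with library totals as the scaling 14.6% of the calls were higher against 46.2%. It was 220 without replicate 2 of the deleted DMSO group, 81 without replicate 2 of the intact doxorubicin group, and 0 without replicate 1 or 3 of the latter or any intact DMSO library.

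Doxorubicin at 1 µM raised p53 target genes and lowered mitotic genes in cells labelled 17p-deleted. Of 32 p53 targets 30 rose, as many adjusted over the list alone, with a median of 2.08. CDKN1A went from 72.7 to 1231 CPM (4.08, SE 0.19), MDM2 from 198 to 2136 CPM (3.43, SE 0.15), BTG2, an antiproliferative gene, rose by 3.85, SE 0.09 and GDF15, a stress-induced cytokine, by 4.78, SE 0.19. Of 35 G2/M genes 32 fell, as many adjusted over the list alone, with a median of -0.92, among them the mitotic kinases PLK1 (-2.20, SE 0.08) and AURKA (-1.92, SE 0.08), while MKI67 was at -0.33, SE 0.20. TOP2A fell by 0.63 (SE 0.09, adjusted p = 1.68e-04) and POLR2A was at 0.29, SE 0.16 (adjusted p = 0.201).

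Interferon-stimulated genes rose in 35 of 36 members, as many adjusted over the list alone, with OAS2 at 3.07, SE 0.11 and MX2 at 2.81, SE 0.10. NF-kB and inflammatory genes rose in 21 of 26 and fell in 1 (23 and 2 adjusted over the list alone), with CXCL8 at 2.88, SE 0.10 and the cytokine IL1A at 3.70, SE 0.14. Of 31 apoptosis regulators 21 rose and 2 fell, the same adjusted over the list alone, including the death receptor genes TNFRSF10A (2.38, SE 0.10) and FAS (2.24, SE 0.12). G1/S and replication genes had 23 of 39 higher and 1 lower (27 and 1 adjusted over the list alone), with the thymidylate synthase gene TYMS at 1.13 and PCNA at 0.93. Antigen presentation genes had 10 of 18 higher (10 adjusted over the list alone), with the peptide transporter gene TAP1 at 1.82. Cytosolic DNA sensing genes had 6 of 9 higher and 0 lower (8 and 1 adjusted over the list alone), with STING1 at 1.51. Mesenchymal genes had 19 of 34 lower and 5 higher (20 and 6 adjusted over the list alone), with the matrix gene SPARC at -0.98 and ACTA2, a smooth muscle actin, at 1.94.

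In all, 3822 genes rose and 2862 fell by edgeR. H19, an imprinted noncoding RNA, went from 1.16 to 78.8 CPM, FAM13C from 0.464 to 18.8 CPM, GPC6, a glypican, from 15.4 to 1.69 CPM and CDH4, a cadherin, from 113 to 16.2 CPM. The 9 lists above passed camera with an estimated correlation, with adjusted p from 2.67e-06 for the p53 targets to 0.0397 for antigen presentation. Histone genes had 10 of 17 lower (11 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation), with H2AC6 at -2.33. At the preset correlation camera gave adjusted p = 0.0839 for homologous recombination genes, 0.797 for stress and unfolded protein responses, 0.706 for cholesterol synthesis, 0.743 for RNA polymerase II subunits, 0.743 for epithelial markers and 0.842 for blood cell markers, none past the threshold. Homologous recombination genes passed once the GC trend was removed, at the preset correlation (adjusted p = 0.00329), with 18 of 26 higher and adjusted p = 0.126 with an estimated correlation. The stress response list had a median of -0.25 and a mean of 0.11, of opposite sign as in the blood cell markers, and its member ATF3, a stress-induced transcription factor, rose by 4.10, SE 0.11.

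**Figure D3:**
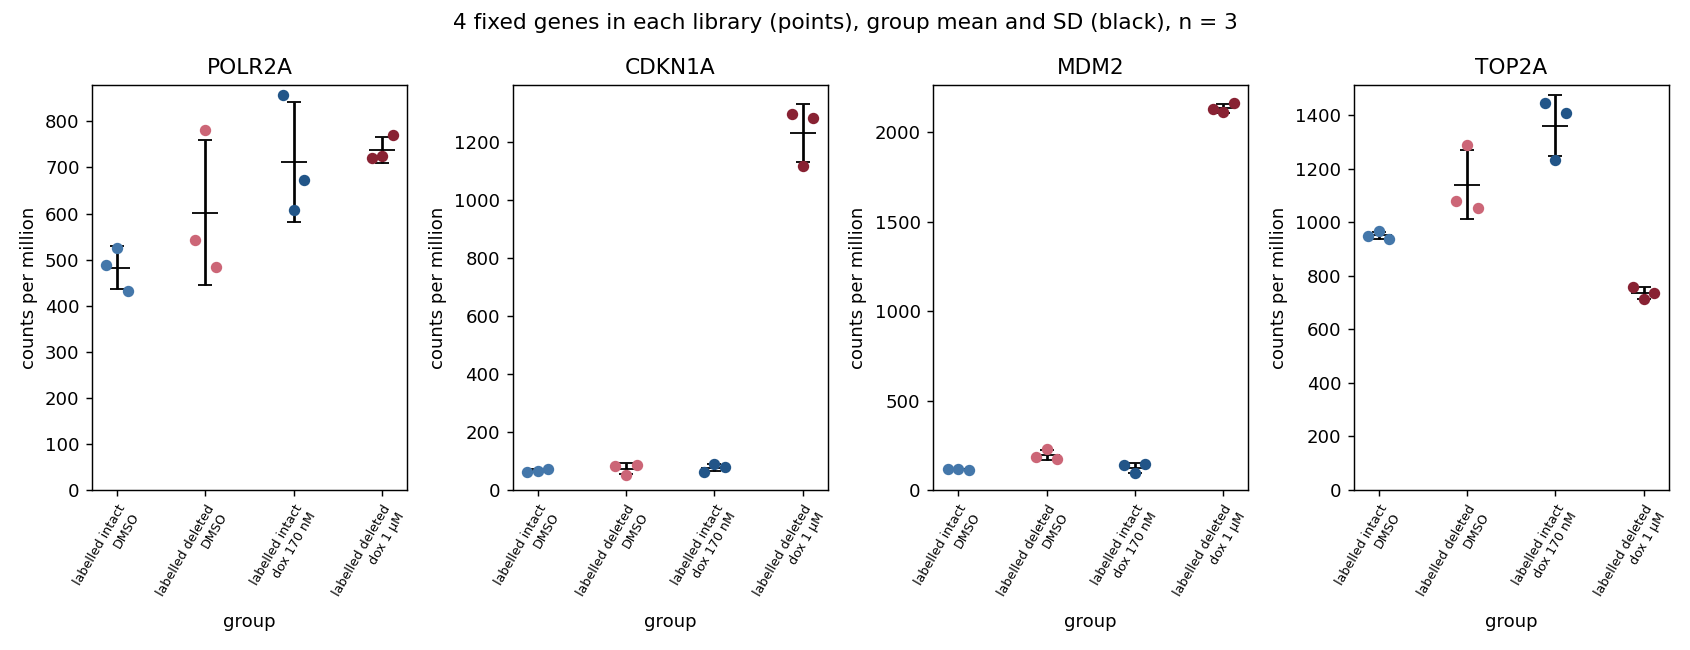
CPM (y axis, from 0) of POLR2A, CDKN1A, MDM2 and TOP2A in each library (points) of the 4 groups (x axis), with the group mean and SD in black, n = 3. CDKN1A averages 1231 CPM in the deleted doxorubicin libraries and 66.6 to 77.2 CPM in the other groups.

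Between treated libraries, those labelled 17p-deleted, which had the higher dose, had higher p53 targets and lower mitotic genes. Of 32 p53 targets 30 were higher and 1 lower, the same adjusted over the list alone, with MDM2 at 4.10, SE 0.16, BTG2 at 3.54, SE 0.09 and DDB2, a DNA damage recognition gene, at 2.76, SE 0.10. Of 35 G2/M genes 31 were lower, as many adjusted over the list alone, with AURKA at -2.15, SE 0.08 and TOP2A at -0.89, SE 0.09. NF-kB genes had 14 of 26 higher and 1 lower, apoptosis regulators 19 of 31 and 3, and G1/S genes 26 of 39 and 2 (14, 20 and 27 higher adjusted over the list alone), with ICAM1 at 2.39, FAS at 2.37 and CHAF1B at 1.17. Antigen presentation genes had 11 of 18 lower and mesenchymal genes 20 of 34 lower and 9 higher (12, 20 and 10 adjusted over the list alone), with TAPBP at -1.41 and MMP2 at -3.96.

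In all, 5655 genes were higher and 4766 lower by edgeR, among them H19 at 8.27, SE 0.31 and DSC3, a desmosomal cadherin, from 0.164 to 34.5 CPM, while CAMK4 was at 28.4 CPM in the intact and 0.662 CPM in the deleted libraries. The 7 lists above passed camera with an estimated correlation, with adjusted p from 8.29e-06 for p53 targets to 0.0471 for G1/S genes and apoptosis regulators. With the GC trend removed these were 0.0843 for G1/S genes, 0.155 for apoptosis regulators, 0.0649 for antigen presentation and 0.155 for mesenchymal genes, and homologous recombination genes passed at the preset correlation (adjusted p = 0.0188, and adjusted p = 0.255 with an estimated correlation). Histone genes (10 of 17 lower, 10 adjusted over the list alone; adjusted p = 0.194 with an estimated correlation), NRF2 targets (9 of 21 lower and 3 higher, 10 and 3 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation) and ribosomal protein genes (25 of 42 lower, 25 adjusted over the list alone; adjusted p = 0.592 with an estimated correlation) passed at the preset correlation alone. Interferon-stimulated genes did not pass as a list, with 11 higher and 13 lower, a median of 0.02 and a mean of -0.25, of opposite sign (adjusted p = 0.334). Signs also differed for anthracycline, stress response and epithelial genes, which did not pass. Genotype and dose cannot be separated in this comparison.

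Whether the doxorubicin effects differed between the genotypes was tested directly. CDKN1A responded more in the deleted libraries by 3.87, SE 0.25, MDM2 by 3.34, SE 0.20, H19 by 6.62, SE 0.45, NSG1 by 6.22, SE 0.45, FAM13C by 5.64, SE 0.30 and FOXS1 by 5.59, SE 0.43. The difference was negative for TOP2A (-1.15, SE 0.13), PLK1 (-2.59, SE 0.12), GPC6 (-2.77, SE 0.27) and EVI2B (-2.81, SE 0.43). It was -3.16, SE 0.67 for PLCXD3, whose level of 0.0312 CPM in the deleted doxorubicin libraries lies near the floor, so that the fitted value depends on the prior count, as does that of NSG1, at 0.0494 CPM in the intact doxorubicin libraries. Of 32 p53 targets 30 responded more in the deleted libraries, as many adjusted over the list alone, and of 35 G2/M genes 33 had a negative difference (35 adjusted over the list alone). NF-kB genes had 20 of 26 with a positive difference, interferon-stimulated genes 23 of 36, apoptosis regulators 15 of 31 and G1/S genes 17 of 39, with 1 apoptosis regulator negative and no member of the others (21, 28, 20 and 22 positive adjusted over the list alone).

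In all, 2235 differences were positive and 1470 negative by edgeR, and with library totals as the scaling 71.3% were positive against 60.3%. The 6 lists above passed camera with an estimated correlation, with adjusted p from 2.02e-06 for p53 targets to 0.0123 for apoptosis regulators and G1/S genes. Histone genes (8 of 17 negative, 9 adjusted over the list alone; adjusted p = 0.104 with an estimated correlation), antigen presentation (4 of 18 positive, 5 adjusted over the list alone; adjusted p = 0.0821 with an estimated correlation) and DNA sensing (3 of 9 positive, 3 adjusted over the list alone; adjusted p = 0.0771 with an estimated correlation) passed at the preset correlation alone. So did mitochondrial mRNAs (0 of 13 past the threshold, 0 adjusted over the list alone; adjusted p = 0.745 with an estimated correlation) and ribosomal proteins (1 of 42 negative, 0 adjusted over the list alone; adjusted p = 0.861 with an estimated correlation), the latter with adjusted p = 0.0526 at the preset correlation once the GC trend was removed. With that trend removed DNA sensing genes also passed with an estimated correlation (adjusted p = 0.0332, 7 of 9 positive), and homologous recombination genes at the preset one (adjusted p = 0.00367, and adjusted p = 0.125 with an estimated correlation). Both libraries with a raised mitochondrial share, at 6.90% and 5.54%, enter this difference, and so do the unequal doses. Median, mean and test differed in sign for the 17p lists, NRF2 targets, stress response, cholesterol synthesis and blood cell markers, which did not pass.

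**Figure D4:**
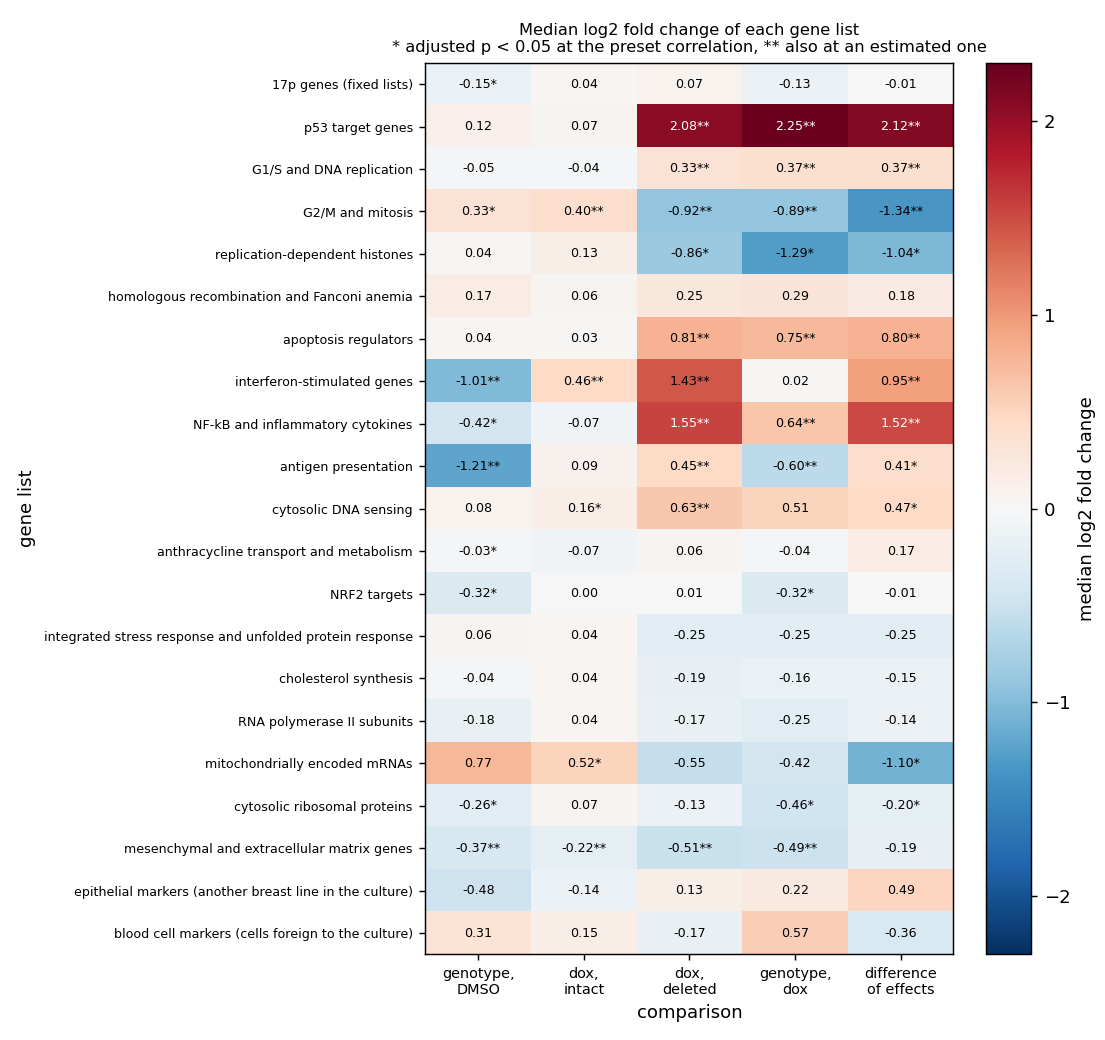
Median log2 fold change (colour and number) of each gene list (y axis) in the 5 comparisons (x axis); 1 asterisk marks an adjusted p under 0.05 at the preset correlation and 2 also at an estimated one. The p53 targets are at 2.08 for doxorubicin in the deleted and 0.07 in the intact libraries.

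Side by side, the doxorubicin effects in the 2 genotypes, which share no control libraries, had a Pearson r of -0.0290 and a Spearman rho of 0.0850 over 21803 genes, which are not independent replicates. Over the 11054 genes with a mean of at least 5 CPM the Pearson r was 0.0886, of the opposite sign, and the Spearman rho 0.105. Of the 6 genes that rose in intact libraries 5 also rose in deleted ones, where independent lists would share 1.05, and of the 7 that fell 3 also fell, against 0.919.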

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

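The tests of the spread and of the dose were chosen after the result was seen, and so was the removal of the GC trend. Groups of 3 were not tested for outlying samples.

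The doxorubicin effects differed between the genotypes for 3705 genes in the edgeR test of the difference. The differences, deleted less intact, were 3.87 for CDKN1A, 3.34 for MDM2, 6.62 for H19, 6.22 for NSG1, 5.64 for FAM13C and 5.59 for FOXS1. They were -1.15 for TOP2A, -2.59 for PLK1, -2.77 for GPC6, -2.81 for EVI2B and -3.16 for PLCXD3. The lists that differed by camera at the preset correlation had median differences of 2.12 for p53 targets, 1.52 for NF-kB genes, 0.95 for interferon-stimulated genes and 0.80 for apoptosis regulators. They were 0.47 for DNA sensing, 0.41 for antigen presentation, 0.37 for G1/S genes, -1.34 for G2/M genes, -1.04 for histones, -1.09 for mitochondrial mRNAs and -0.20 for ribosomal proteins. With an estimated correlation 6 of these 11 lists passed. The others were DNA sensing, antigen presentation, histones, mitochondrial mRNAs and ribosomal proteins (adjusted p = 0.0771, 0.0821, 0.104, 0.745 and 0.861). With the GC trend removed DNA sensing passed with an estimated correlation (adjusted p = 0.0332), and ribosomal proteins did not pass at the preset one either (adjusted p = 0.0526).

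Drug labels were regrouped within each genotype in 100 of 200 possible ways, the real one included. The real grouping gave 3705 genes, 5 of the 100 gave as many and the highest other gave 4670, so chance was not excluded by this count. A first draw of 60, later extended to 100, had 4. This count says little, because regroupings that keep the drug labels of the deleted libraries hold the doxorubicin effect of those libraries: 1 that exchanged the intact labels gave 4670 genes, and 8 that mixed them gave 2783 to 4472. The 10 that mixed the deleted labels alone and the 80 that mixed both gave 0 genes each. Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes, with 7618 for genotype in DMSO, 13 and 6684 for doxorubicin in intact and deleted cells, 10421 for genotype in doxorubicin, and 0 as the highest other.

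The p53 targets rose with doxorubicin in the deleted libraries by a median of 2.08 and were at 0.07 in the intact ones. With the GC trend removed their median difference was 2.19, which argues against that trend as the whole cause. The median upper 95% bound of their change in the intact libraries was 0.42, which argues against an equal rise hidden by the spread. The doses differed 5.88 times in every treated library, so the higher dose and the genotype cannot be told apart. Either may account for the difference, and so may other differences between the cell populations, such as the shifts of chromosome medians.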

How the results depend on the processing

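The GC and 2-library alternatives and the correlation over genes of at least 5 CPM were chosen after seeing the data, as was the test of exposure. Requiring a 2-fold change as well left 2651 genes for the genotype effect in DMSO, 2 for the doxorubicin effect in 17p-intact cells, 2921 for the doxorubicin effect in 17p-deleted cells, 4926 for the genotype effect in doxorubicin and 1984 for the difference of the doxorubicin effects, by construction. Under the other alternatives, single libraries left out included, each of these counts but that for intact cells stayed within 1.5 times. That count, 13 by edgeR, was 48 with library totals, 196 without a filter, 65 with a filter of 1 CPM in 3 libraries, 467 with DESeq2, 25 with limma-voom, 0 with only the groups compared, 427 with the GC trend removed and 195 without the 2 libraries of the highest mitochondrial share. Leaving out single libraries gave 0 to 220. It was 220 without replicate 2 of the deleted DMSO group (4 and 5 without 1 and 3), 81 without replicate 2 of the intact doxorubicin group, 3 without each deleted doxorubicin library and 0 without any other. With the GC trend removed all 13 genes still passed, and of 3 lists that passed with an estimated correlation, 2 moved in the same direction as in the deleted libraries and 1 in the opposite one. Whether these libraries were exposed to the drug is not decided by that, since untreated cultures can differ too. Except for the GC trend, the cause of the changes in this count was not tested.

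The 17p dosage in DMSO, the median of 17p less that of all other genes, was -0.17. It was -0.192 with the fixed lists, -0.192 with genes of at least 5 CPM, -0.0695 with no filter, where more genes of low counts enter, -0.116 with the GC trend removed, -0.108 without the 2 libraries, and -0.197 to -0.106 over single libraries left out, the latter without replicate 2 of the deleted DMSO group. A separate statistic, the mean 17p score over both treatments, had exact permutation p = 0.24. Its exact p was 0.02 with the fixed lists, with genes of at least 5 CPM, without the 2 libraries, and without replicate 1 of the intact doxorubicin group, where the dosage was -0.170. It was 0.705 with library totals, 0.295 and 0.265 without replicates 1 and 3 of the intact DMSO group, 0.245 without replicate 1 of the deleted DMSO group, and 0.05 to 0.24 under the other alternatives by the same exact test. The permutation p of 17p less other genes was not computed under these alternatives, and the cause of these changes was not tested. Of 105 tests of a list, 21 lists in 5 comparisons, camera called 45 at the preset correlation, of which 28 passed with an estimated one. The fry test, which asks whether the genes of a list move 1 way and sets them against no other genes, called 54, of which 41 were among those 45 and 13 were not. The Pearson r of the doxorubicin effects in the 2 genotypes side by side was 0.00920 with the filter of 1 CPM, where fewer genes are tested, 0.0886 with genes of at least 5 CPM, and -0.0660 to -1.08e-04 over libraries left out. With library totals the median of all genes in the difference went from -0.03 to 0.08.

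With the replicate number as a block the count for doxorubicin in intact cells was 0, and the others were 6720, 5896, 9688 and 2913. A check gave no sign that the numbers pair the libraries: 1 of 18 same-number pairs had a correlation of deviations over 0.1, and 5 of 12 libraries correlated best with their own number. It cannot exclude pairing, since trends of single libraries may hide it. Replicate 2 of the deleted DMSO and replicate 1 of the intact doxorubicin group, of unlike number, correlated at 0.33. Of 333 results for named genes, 218 were past the threshold and 193 stayed so under every alternative run, and 0 reversed. Apart from the fixed set, genes past the threshold were named for large changes or low p in the same main fit. This favours calls that stay, so these counts are not a test of robustness. The call for TOP2A, genotype effect in DMSO, was lost under most alternatives, with adjusted p up to 0.271. At these depths the simulated fits called few 1.5-fold differences of effect, 2 of 100.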

Other observations

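The tests on chromosome dosage, scaling, exchanged libraries and partial loss were chosen after the result was seen, and so was the removal of the GC trend.

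Some genes not named so far also moved with 1 µM doxorubicin in the deleted libraries. NLRP1, an inflammasome sensor gene on 17p, rose by 2.09, SE 0.11, and NTN1, which encodes the guidance protein netrin and also lies on 17p, by 3.03, SE 0.18. XDH, which encodes xanthine dehydrogenase, rose by 2.49, SE 0.12 and AKR1B10, an aldo-keto reductase gene, by 4.40, SE 0.32, and TXNRD1, a thioredoxin reductase gene, was at -0.92, SE 0.08.

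RNA from 17p was not near the level of a loss of 1 of 2 copies in the libraries labelled 17p-deleted. A scaling shifts all genes of a library alike, so it cannot hide a loss in a difference between sets of genes. Such differences in DMSO were -0.17 for 17p less other genes and 0.11 for 17p less 17q. The latter cannot show a loss that 17q shares. With the GC trend removed 17p less other genes was -0.12, which argues against that trend as what hides such a loss. 0 libraries lay nearer the other genotype in 17p less 17q, and 0 correlated best over all genes with a library of the other genotype, which argues against single libraries exchanged between the groups. A loss in part of the cells, or from more than 2 copies, may give the difference of -0.17, and cannot be told apart from other causes because 17q, which the labels do not name as lost, was lower still.

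Chromosome medians were shifted between the genotypes, in DMSO and doxorubicin by 0.52 and 0.55 for chromosome 21, -0.49 and -0.37 for chromosome 22, and -0.26 and -0.21 for chromosome 17. The shift was uneven along chromosome 17. Its 2 Mb windows of at least 5 genes ran in DMSO from -0.46 at 74 to 76 Mb to 0.33 at 68 to 70 Mb. Windows within the other chromosomes were not examined. Over 23 chromosomes the medians correlated with Pearson r = 0.966 (0.943 without the 2 farthest) and Spearman rho = 0.941, each with permutation p = 1e-05, the smallest possible. Both sets of medians compare the same cell populations, so any lasting difference between them, from dosage or not, gives a high r. The permutation p therefore does not bear on dosage. The range over chromosomes was 1.008, and 0.935 with the GC trend removed, which argues against that trend; it was 0.0835 and 0.169 in the doxorubicin comparisons. A stable difference in gene dosage between the cell populations is a candidate explanation, as a hypothesis found and tested on the same data; copy number was not measured here.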
